A study of Cyprinodon variegatus with 36 samples.

How the data were processed

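Whole-body RNA was sequenced from 36 pools of the sheepshead minnow Cyprinodon variegatus, an estuarine killifish. The pools came from 3 life stages, which per the series' design were at most 15 h post-fertilization (embryonic), 24 h post-hatch (post-hatch) and 4 d post-hatch (post-larval) at the start. Each stage was held for 48 h under normoxia (at least 5 mg/L oxygen) or hypoxia (at most 2 mg/L), with or without a 12.5% high energy water accommodated fraction (HEWAF) of Macondo well oil, that is, oil dispersed into seawater by vigorous mixing. Every one of the 12 groups held 3 libraries, each from 10 pooled animals kept at 30 ppt salinity and 30 °C. The labels call the treatments triplicates without saying whether each had its own tank, so p-values measure the spread between these pools. Measured oil, given in the labels as tPAH29 with no unit, differed between groups. In embryos it was 128.61 ± 6.94 under normoxia and 168.05 ± 27.8 under hypoxia. Post-hatch fish had 69.79 ± 2.18 and 115.39 ± 4.4, and post-larval fish 82.64 ± 4.85 and 97.48 ± 4.31. Stage and dose therefore cannot be separated, and oil under hypoxia was a higher measured dose than oil under normoxia at each stage.

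Per the labels' protocols, polyA libraries were made with a stranded mRNA kit. CASAVA and FastQC are the only tools named in the submitters' processing notes, with no version; the aligner, the counting program and whether counting used strand are not given in the sources used here. The authors deposited 1 table per library with 25075 genes. Per the file headers, it holds counts of reads as whole numbers for each gene, its exons, its introns and its exon junctions, each as all reads and as uniquely placed reads. Per the file headers, the deposited tables also hold TPM and RPKM values computed by the authors, and for each gene 2 fractions, the share of its reads in introns and the unique share of its exon reads; TPM and RPKM were not used for any test. All 25075 gene identifiers were in the NCBI gene table of the assembly C_variegatus-1.0, and 24678 genes had the same start and end there, so coordinates are those of that assembly. No genome sequence was used. Of these genes, 10078 had a symbol and 14530 had only a LOC number with no product name, which kept cytochrome P450 1 genes, lactate dehydrogenase A and hemoglobins from being identified by symbol.

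The total gene read counts, which include intron reads, were tested with edgeR 4.0.16 in R 4.3.3. Each stage was fitted separately with 1 mean for each of its 4 groups, TMM normalisation, filterByExpr at its defaults (minimum count 10, minimum total count 15), and the quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The filter left 19559 embryonic, 21812 post-hatch and 21198 post-larval genes, holding 99.934%, 99.977% and 99.951% of the reads. In each stage, oil alone, hypoxia alone and oil with hypoxia were each set against the normoxic control, and oil with hypoxia against hypoxia alone (oil under hypoxia). The interaction compared the oil effect between oxygen levels. A further fit of all 36 libraries (21877 genes) compared the normoxic controls between stages and tested, with 2 degrees of freedom, whether each effect was equal in the 3 stages.

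Lists of genes (36, fixed before the data were examined) were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists with at least 3 measured members, and again with the correlation estimated from the data. A pair of these lists, cytosolic ribosomal proteins and nuclear oxidative phosphorylation, had been fixed by product name and were matched by symbol once the tables were seen, before any test. With an estimated correlation, the calls that held were those of photoreceptor genes in embryos under oil with hypoxia and under oil under hypoxia, of aryl hydrocarbon receptor (AHR) target genes in embryos under oil under hypoxia and in post-hatch fish under oil alone and oil under hypoxia, and of circadian clock genes between the older control stages. The genes rgn, mcm2 and des were picked from those called at every stage. All other genes named in the text followed a rule set before the data were examined. It took, per comparison against the normoxic control, up to 5 genes with the largest rise and 5 with the largest fall among called, symbol-bearing genes with a mean of at least 5 CPM and groups that did not overlap (all 3 libraries on 1 side of all 3 controls), then up to 2 called members of each leading list to about 30 genes, and ahrr, tiparp, egln3 and vegfa in every comparison. For the remaining tests it took up to 5 genes with the smallest p. Values in CPM are counts scaled to a common library size with TMM factors, as mean ± SD over 3 libraries, and fold changes are log2 with their standard error (SE).

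Depth was 12018712 to 23042839 gene reads in embryonic, 21740789 to 30080209 in post-hatch and 13263290 to 17762109 in post-larval libraries, of which at least 97.0% were uniquely placed. The biological coefficient of variation, the spread between replicates beyond counting noise, was 0.274 in embryos, 0.112 in post-hatch and 0.185 in post-larval fish. The analysis was tested on simulated counts with 200 genes changed by known folds, drawn with the real means, library sizes and spread. For oil alone, edgeR recovered 14.9% of the 2-fold changes in embryos, 85.1% in post-hatch and 59.7% in post-larval fish, and 68.2%, 100% and 95.5% of the 4-fold changes. It called 1, 4 and 8 unchanged genes, and DESeq2 1.42.0 called 28, 19 and 27. Of the 2-fold changes DESeq2 recovered 37.3%, 91% and 73.1%, so it called more changed genes and also more unchanged ones. No replicate pair of a group agreed within sampling noise (chi-square per degree of freedom at least 8.18).

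The labels number replicates 1 to 3 in every group. Same-numbered embryonic libraries deviated from their group means together in hypoxia alone (r over genes of 0.77, 0.42 and 0.78). They also did in oil with hypoxia (0.63, 0.14 and 0.68) and in oil under hypoxia (0.65, 0.17 and 0.70). Counts of genes from a fit with the replicate number as a block therefore stand beside those results. For replicate 2, however, a differently numbered library agreed more closely in each of these comparisons, with r of 0.44, 0.30 and 0.27. Its number therefore does not mark a pair. The p-values of genes and lists, and the fits that left out 1 library, are without the block. Every embryonic call of a gene named by the rule held with the block. In every other comparison at least 1 of the 3 pairs had r of at most 0.1. The embryonic interaction, which spans both kinds of pair, is also given with the block.

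The alternatives fixed in advance were median-of-ratios (RLE) factors in edgeR, DESeq2, no low-count filter, unique gene reads, the replicate block, 1 fit of all 36 libraries and leaving out each library in turn. Counting exon reads only, and leaving out 2 embryonic libraries that stood apart, were added after seeing the data. Of the 185 genes named by the rule, 5 overlap another gene on the same strand and 14 a gene on the opposite strand, and 7 had under 90% uniquely placed reads; such genes are reported as uncertain where they are named. Libraries of unchanged groups against shared controls were simulated 20 times.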

Results

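Oil, hypoxia and their combination were each compared with the normoxic control at 3 life stages of the sheepshead minnow. In embryos, the combination changed 1076 of 19559 genes, against 66 for oil and 42 for hypoxia. Post-hatch fish had 1819 genes changed by oil, 7400 by hypoxia and 8276 by both, of 21812 tested. Post-larval fish had 1378, 2232 and 4137 of 21198. On simulated counts, 14.9% of 2-fold changes were recovered in embryos, 85.1% in post-hatch and 59.7% in post-larval fish, so these counts do not rank the stages by how strongly they responded. The embryonic counts do not rank the treatments either. For oil, hypoxia and both they were 276, 603 and 1916 in DESeq2, and 1353, 1133 and 3148 in 1 fit of all 36 libraries. Without normoxic control 3 and hypoxic control 3, an alternative added after seeing the data, they were 4994, 71 and 3535, so that oil had more genes than both stressors. The post-hatch counts were 356, 1805 and 3579 in the fit of all 36 libraries. That fit takes 1 spread per gene over all stages and not the spread of each stage.

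**Figure D1:**
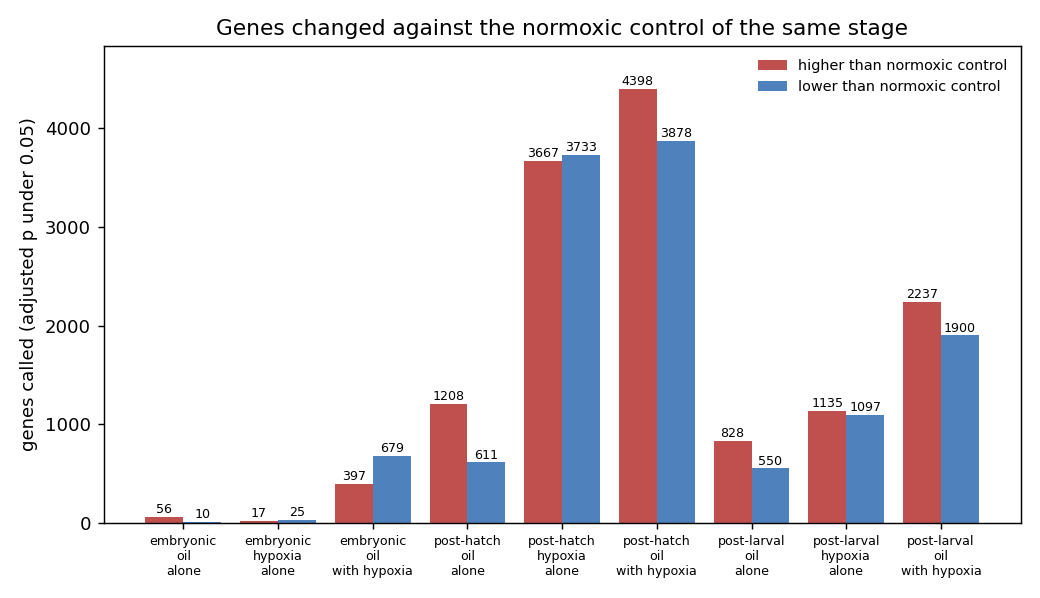
Bars give the number of genes with an adjusted p under 0.05 (y axis) higher (red) or lower (blue) than the normoxic control of the same stage, for each stage and treatment (x axis). The most were called in post-hatch fish under oil with hypoxia, 4398 higher and 3878 lower.

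The libraries of each treatment lay together in post-hatch fish, while 1 normoxic and 1 hypoxic control of the embryos lay apart from their replicates on the first principal component. Embryonic libraries under oil with hypoxia were spread from -55.3 to 27.5 on it. In post-larval fish replicate 3 under oil with hypoxia, at 27.8, lay apart from the others of its group, at -13.3 and -5.34. The first principal component held 47.7% of the variance in embryos, 35.1% in post-hatch and 25.7% in post-larval fish. Correlations between replicates, across genes, were 0.904 to 0.989 in embryos, 0.984 to 0.994 in post-hatch and 0.971 to 0.985 in post-larval fish.

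**Figure D2:**
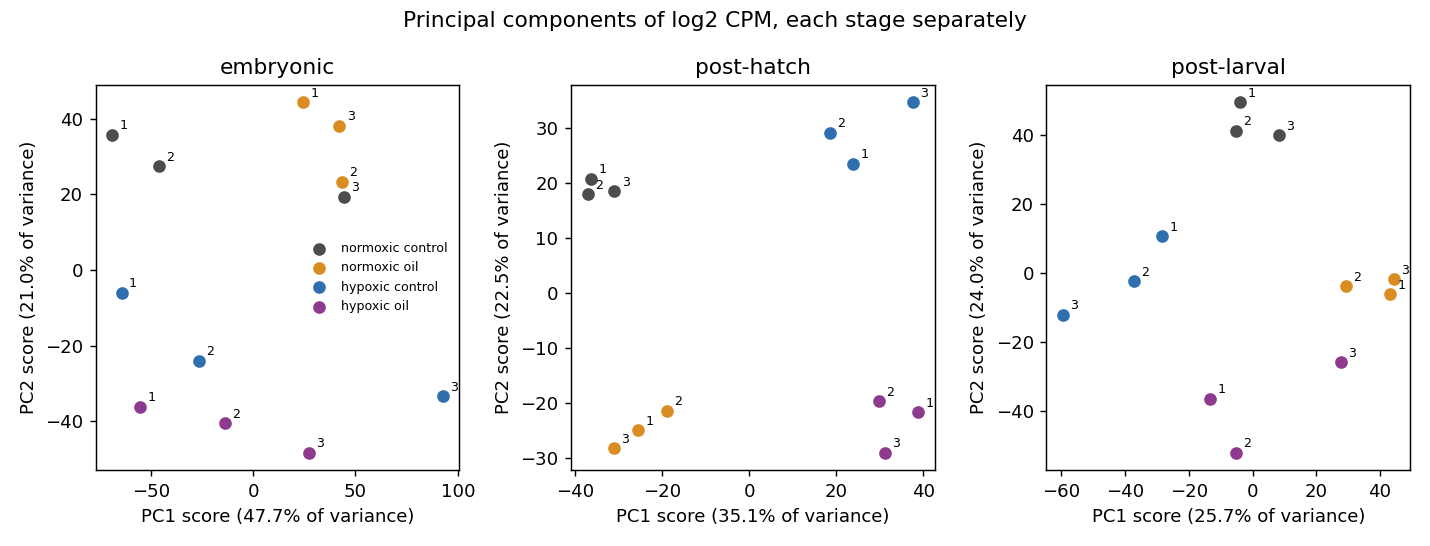
Points are libraries, coloured by treatment and numbered by replicate, on the first (x axis) and second (y axis) principal component scores of log2 CPM in each stage. Replicate 3 of the embryonic normoxic control, at 44.5, and of the hypoxic control, at 92.7, lay far from their replicates on the first component, at -68.8 and -46.1 and at -64.2 and -26.5.

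Between the control groups, the lists of digestive enzyme and immune cell genes were higher after hatching and that of cell cycle genes was lower, at the preset correlation only (adjusted p = 0.2, adjusted p = 0.357 and adjusted p = 0.357 with an estimated correlation). The muscle AMP deaminase ampd1, the mitochondrial uncoupling protein ucp1 and the pancreatic phospholipase pla2g1b rose after hatching, and the serine dehydratase sds and the transmembrane protease tmprss9 fell. From the post-hatch to the post-larval stage, the AP-1 subunits fosl1 and fosb and the stress-induced growth inhibitor ddit4 rose, as did 6 of 9 circadian clock genes, while the collagen chaperone serpinh1 and fibrillar collagen col5a2 fell. In normoxic controls, 14074 of 21877 genes differed between post-hatch and embryonic fish (7335 higher, 6739 lower) and 6803 between post-larval and post-hatch fish (3643 higher, 3160 lower). Expression of ampd1 (C_variegatus-1.0 scaffold NW_015150612.1, 1135558 to 1153611) was 0.522 ± 0.279 CPM in embryos and 2160 ± 212 CPM after hatching, a log2 change of 11.94 ± 0.48 (adjusted p = 6.54e-18). For sds the log2 change was -6.61 ± 0.59 (adjusted p = 1.16e-10). Of 8 digestive enzyme genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a list adjusted p of 0.00013 and adjusted p = 0.2 with an estimated correlation. All 14 immune cell genes were higher after hatching (14 adjusted over the list alone), with a list adjusted p of 0.00312 and adjusted p = 0.357 with an estimated correlation. Of 40 cell cycle and DNA replication genes, 39 fell (39 adjusted over the list alone), with a list adjusted p of 3.74e-15 and adjusted p = 0.357 with an estimated correlation. Later, ddit4 went from 35.3 ± 1.16 to 436 ± 125 CPM, a log2 change of 3.63 ± 0.26 (adjusted p = 3.44e-11). The log2 changes were 4.61 ± 0.47 for fosl1 (adjusted p = 1.72e-08), -3.21 ± 0.29 for serpinh1 (adjusted p = 3.31e-09) and -2.48 ± 0.43 for col5a2 (adjusted p = 6.67e-05). Of 9 circadian clock genes, 6 rose (7 adjusted over the list alone) and the list rose (adjusted p = 8.54e-08, and adjusted p = 0.00407 with an estimated correlation). The labels give ages of 2.5 days post-hatch for post-hatch and 6 days for post-larval fish. Hour of sampling was not compared between stages, so stage and hour are not separated for these genes. Of 20 cartilage and bone genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone), with a list adjusted p of 3.97e-09 and adjusted p = 0.185 with an estimated correlation.

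In embryos exposed to oil alone, 66 genes were called. Among those that rose were gchfr, the feedback regulator of the enzyme that starts tetrahydrobiopterin synthesis, selenbp1, a selenium-binding methanethiol oxidase, and abcc2, an exporter of conjugated compounds into bile. The glutathione-degrading enzyme chac1, a target of the unfolded protein response, also rose, and elastin (eln), the elastic fibre protein of vessels, fell. Oil raised 56 genes and lowered 10 of 19559, of which 59 changed at least 2-fold. The count was 508 with the replicate block. The split was 203 higher and 73 lower in DESeq2, 633 and 720 in the fit of all 36 libraries, and 2466 and 2528 without the 2 controls that stood apart. Expression of gchfr (NW_015151381.1, 94788 to 99126) went from 6.86 ± 1.16 to 41.1 ± 10.5 CPM, a log2 change of 2.58 ± 0.26 (adjusted p = 0.00118). That of selenbp1 (NW_015151940.1, 18841 to 29790) went from 25.6 ± 3.23 to 143 ± 37 CPM, a log2 change of 2.48 ± 0.21 (adjusted p = 0.000352), and abcc2 had a log2 change of 2.26 ± 0.26 (adjusted p = 0.00345). Log2 changes were 1.94 ± 0.36 for chac1 (adjusted p = 0.0471), a call lost in 10 of 12 fits that each left out 1 library (highest adjusted p 0.287), and -2.17 ± 0.33 for eln (adjusted p = 0.0153), lost in 5 (highest 0.126). No list had a member called except those with chac1. The 50 nuclear oxidative phosphorylation genes had a median log2 change of 0.62 and none called over all genes (0 adjusted over the list alone; list adjusted p = 6.28e-15; adjusted p = 0.431 with an estimated correlation). The 14 targets of NRF2, the transcription factor of the antioxidant response, had none called over all genes and 4 higher adjusted over the list alone (list adjusted p = 0.0228; adjusted p = 0.431 with an estimated correlation). Leaving out 1 library moved the count of 66 to between 18 and 202. It was 18, 23 and 42 without normoxic control 1, 2 and 3, 35 and 23 without normoxic oil 2 and 3, 202 without hypoxic control 3 and 39 without hypoxic oil 2.

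Under hypoxia alone in embryos, cell cycle genes rose and photoreceptor genes fell as lists, at the preset correlation only (adjusted p = 0.0595 and adjusted p = 0.072 with an estimated correlation). Ornithine decarboxylase (odc1), which starts polyamine synthesis, the methionine and leucine tRNA ligases mars and lars and the replicative helicase subunits mcm3 and mcm6 rose. The small heat shock protein of muscle hspb6, the muscle lamin-binding protein mlip, the liver enzyme agxt and cone arrestin (arr3), which shuts off cone opsins, fell. The oxygen sensor egln3, a prolyl hydroxylase whose transcription follows hypoxia-inducible factor (HIF), fell as well. Hypoxia raised 17 genes and lowered 25. With the replicate block it raised 334 and lowered 307, and in DESeq2 332 and 271. Expression of odc1 went from 54.4 ± 6.77 to 128 ± 19.1 CPM, a log2 change of 1.23 ± 0.17 (adjusted p = 0.0161). On the log2 scale the change was 1.05 ± 0.15 for mcm3 (adjusted p = 0.0191), -1.96 ± 0.23 for hspb6 (adjusted p = 0.00986), -1.88 ± 0.19 for mlip (adjusted p = 0.00765) and -1.44 ± 0.18 for arr3 (adjusted p = 0.00986). The change of 1.38 ± 0.23 for mars (adjusted p = 0.0424) lost its call in 10 of 12 fits that each left out 1 library (highest adjusted p 0.208), and odc1, mcm3, mcm6, agxt and egln3 each lost theirs in 3 (highest 0.142). For egln3 (NW_015150617.1, 509592 to 516578), expression fell from 74.2 ± 13.4 to 22.3 ± 6.1 CPM, a log2 change of -1.74 ± 0.25 (adjusted p = 0.0191). Of 40 cell cycle genes 2 rose (13 adjusted over the list alone), with a list adjusted p of 4.59e-17 and adjusted p = 0.0595 with an estimated correlation. Of 17 photoreceptor genes 1 fell (8 adjusted over the list alone), with a median of -0.88, a list adjusted p of 2.78e-14 and adjusted p = 0.072 with an estimated correlation. Without hypoxic control 2 the count of 42 was 0 in edgeR (2507 genes had an unadjusted p under 0.05 with all libraries, and DESeq2 called 603), while the log2 changes were then -1.80 for mlip (adjusted p = 0.0759), 1.17 for odc1 (adjusted p = 0.118) and -1.60 for egln3 (adjusted p = 0.142). The count was 11 and 2 without normoxic control 1 and 2 and 23 without normoxic oil 3.

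In embryos under oil with hypoxia, 15 of 17 photoreceptor genes fell and 13 of 40 cell cycle genes rose, the second list at the preset correlation only (adjusted p = 0.0525 with an estimated correlation). The muscle chloride channel clcn1, hspb6, the purine enzyme gmpr and the cone genes pde6h and arr3 fell. The AHR repressor ahrr, itself a target of the receptor that binds oil hydrocarbons, and glutathione reductase (gsr), which keeps glutathione reduced, rose with gchfr. The circadian repressor nr1d2 and egln3 fell. The combination raised 397 genes and lowered 679, and 606 changed at least 2-fold. With the replicate block it changed 2330, and without the 2 controls that stood apart it raised 1881 and lowered 1654. Expression of clcn1 (NW_015150501.1, 545156 to 590595) fell from 23.5 ± 1.58 to 0.634 ± 0.441 CPM, a log2 change of -5.28 ± 0.49 (adjusted p = 0.000182). For hspb6 (NW_015150596.1, 662274 to 664097) the log2 change was -3.63 ± 0.26 (adjusted p = 3.21e-05), and for gmpr it was -3.60 ± 0.36 (adjusted p = 0.000245). Expression of arr3 (NW_015151741.1, 109802 to 116921) fell to 14.1 ± 1.65 CPM, a log2 change of -2.89 ± 0.19 (adjusted p = 1.52e-05). The log2 change was -3.49 ± 0.46 for pde6h (adjusted p = 0.00135), -1.72 ± 0.16 for nr1d2 (adjusted p = 0.000186) and 1.22 ± 0.17 for gsr (adjusted p = 0.00159). Of 17 photoreceptor genes 15 fell (17 adjusted over the list alone), with a median log2 change of -1.87 (list adjusted p = 5.46e-36; adjusted p = 0.00548 with an estimated correlation). Of 40 cell cycle genes 13 rose (23 adjusted over the list alone), with a list adjusted p of 4.96e-14 and adjusted p = 0.0525 with an estimated correlation. Of 17 plasma proteins of the liver 4 fell (10 adjusted over the list alone), with a list adjusted p of 3.34e-06 and adjusted p = 0.463 with an estimated correlation. The count of 1076 was 443 and 500 without normoxic control 1 and 2, 1688 without hypoxic control 3, and 555 and 512 without hypoxic oil 2 and 3.

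Among embryos held in hypoxia, oil raised gchfr and selenbp1 again and lowered elastin, arr3 and the scavenger receptor mrc1, which clears glycoproteins in macrophages and vessel linings. The muscle genes hspb6 and pfkm (phosphofructokinase), the purine enzyme gmpr and the ATP-sensitive potassium channel kcnj11 had a lower oil effect in hypoxia than in normoxia. Measured oil was higher in hypoxia, so this difference holds dose as well as oxygen. Oil under hypoxia raised 39 genes and lowered 52, against 81 and 167 with the replicate block, and changed 446 in the fit of all 36 libraries and about 3.4e+02 in DESeq2. Without the 2 controls that stood apart it changed 138, and the interaction 70. Log2 changes were 2.50 ± 0.26 for gchfr (adjusted p = 0.000963), -2.79 ± 0.33 for eln (adjusted p = 0.00332) and -2.16 ± 0.21 for mrc1 (adjusted p = 0.000714). Of 17 photoreceptor genes 3 fell (12 adjusted over the list alone), with a list adjusted p of 1.05e-25 and adjusted p = 0.018 with an estimated correlation. The 5 AHR target genes had 1 member higher over all genes and 3 adjusted over the list alone (list adjusted p = 1.35e-05; adjusted p = 0.0246 with an estimated correlation). The interaction reached 22 genes, 21 of them lower. It reached 226 with the replicate block (17 higher, 209 lower), 261 in DESeq2, and 477 in the fit of all 36 libraries (104 higher, 373 lower). Mean expression of gmpr was 146 ± 17.3 CPM without and 339 ± 97.4 CPM with oil in normoxia, and went from 55.3 ± 29.4 to 12 ± 1.17 CPM in hypoxia, an interaction of -3.41 ± 0.47 (adjusted p = 0.0164). The interaction was -2.50 ± 0.33 for hspb6, -2.64 ± 0.36 for pfkm and -1.56 ± 0.22 for kcnj11, each with an adjusted p of 0.0164, and each call was lost in at least 4 of 12 fits that left out 1 library (highest adjusted p 0.0931). The oil under hypoxia count of 91 was 59 without hypoxic control 1 and 48, 43 and 59 without hypoxic oil 1, 2 and 3. The interaction count of 22 was 14, 6 and 12 without normoxic control 1, 2 and 3, 5, 39 and 5 without normoxic oil 1, 2 and 3, 36 without hypoxic control 3, and 11 and 5 without hypoxic oil 1 and 2.

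Oil alone in post-hatch fish raised 3 of 5 AHR target, 3 of 6 red cell, 7 of 19 cholesterol synthesis, 8 of 14 inflammatory and 5 of 9 circadian clock genes. With an estimated correlation the AHR list kept its call (adjusted p = 0.00329) and the others lost it (adjusted p = 0.0548, 0.234, 0.151 and 0.117). The AHR repressor ahrr and the AHR-induced ADP-ribosyltransferase tiparp rose, along with the matrix protease mmp9, the transcription factor klf13 and gadl1, a decarboxylase that makes beta-alanine. The red cell anion exchanger slc4a1, the mitochondrial hypoxia-induced protein higd1a, the clock output factor tef and gsr rose too. Among the genes that fell were the phosphodiesterase gdpd2 and the DNA repair enzyme aptx. Oil raised 1208 genes and lowered 611, of which 335 changed at least 2-fold. In the fit of all 36 libraries it raised 276 and lowered 80. Expression of gadl1 (NW_015150587.1, 492939 to 507802) rose from 3.71 ± 0.303 to 42 ± 16.5 CPM, a log2 change of 3.50 ± 0.24 (adjusted p = 5.35e-07). That of ahrr (NW_015150564.1, 260060 to 345324) rose from 18.9 ± 1.62 to 58.7 ± 5.41 CPM, a log2 change of 1.63 ± 0.10 (adjusted p = 6.06e-08). On the log2 scale the change was 2.00 ± 0.11 for klf13 (NW_015151662.1, 85448 to 111044; adjusted p = 2.18e-08), 2.01 ± 0.30 for mmp9 (adjusted p = 0.000636), 1.23 ± 0.12 for slc4a1 (adjusted p = 1.18e-05) and 1.34 ± 0.13 for higd1a (adjusted p = 1.66e-05). For tef it was 1.14 ± 0.11 (adjusted p = 2.14e-05), and for gdpd2 it was -0.85 ± 0.12 (adjusted p = 0.00036). Of 5 AHR target genes 3 rose (3 adjusted over the list alone; list adjusted p = 9.65e-11; adjusted p = 0.00329 with an estimated correlation). Of 19 cholesterol synthesis genes 7 rose (11 adjusted over the list alone), with a list adjusted p of 4.55e-09 and adjusted p = 0.234 with an estimated correlation. Of 14 inflammatory and acute phase genes 8 rose (11 adjusted over the list alone), with a list adjusted p of 1.78e-08 and adjusted p = 0.151 with an estimated correlation. Of 14 NRF2 target genes 5 rose (6 adjusted over the list alone), with a list adjusted p of 9.96e-05 and adjusted p = 0.0548 with an estimated correlation. Of 6 red cell genes 3 rose (3 adjusted over the list alone), with a list adjusted p of 0.000275 and adjusted p = 0.0548 with an estimated correlation. Of 9 circadian clock genes 5 rose (5 adjusted over the list alone), with a list adjusted p of 9.84e-06 and adjusted p = 0.117 with an estimated correlation. The count of 1819 was 1095, 1100 and 1208 without normoxic control 1, 2 and 3 and 1148 without normoxic oil 1.

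Hypoxia alone raised 8 of 14 genes of beta-oxidation and PPAR targets in post-hatch fish, along with 30 of 39 cell cycle, 34 of 62 ribosomal protein and 11 of 13 mitochondrially encoded genes, and lowered 15 of 19 neuronal and synaptic genes. Each list lost its call with an estimated correlation (adjusted p = 0.52 for the first and 0.769 for the others). The muscle fatty acid importer of mitochondria cpt1b, the lipase inhibitor angptl4, which fasting induces, and the creatine synthesis enzyme gatm rose. Fatty acid synthase (fasn) fell, as did the muscle ubiquitin ligase fbxo32, the autophagy receptor calcoco1, the deubiquitinase usp13 and snap25, which drives vesicle fusion at synapses. Hypoxia raised 3667 genes and lowered 3733, of which 625 changed at least 2-fold, and 1805 were changed in the fit of all 36 libraries. Expression of angptl4 (NW_015151448.1, 277368 to 286469) rose from 28.4 ± 4.76 to 95.2 ± 11.8 CPM, a log2 change of 1.74 ± 0.14 (adjusted p = 4.9e-06). That of fbxo32 (NW_015150711.1, 567976 to 574733) fell from 256 ± 30 to 72.1 ± 5.43 CPM, a log2 change of -1.83 ± 0.22 (adjusted p = 6.27e-05). The log2 change was 1.76 ± 0.13 for cpt1b (adjusted p = 4.9e-06), 1.82 ± 0.25 for gatm (adjusted p = 0.000154), -1.56 ± 0.10 for fasn (adjusted p = 2.63e-06) and -1.75 ± 0.20 for calcoco1 (adjusted p = 4.47e-05). For snap25 it was -0.71 ± 0.10 (adjusted p = 0.000155). Of 14 genes of beta-oxidation and PPAR targets 8 rose (8 adjusted over the list alone), with a list adjusted p of 2.56e-07 and adjusted p = 0.52 with an estimated correlation. Of 39 cell cycle genes 30 rose and 1 fell (33 and 1 adjusted over the list alone), with a list adjusted p of 2.67e-10 and adjusted p = 0.769 with an estimated correlation. Of 62 cytosolic ribosomal protein genes 34 rose (39 adjusted over the list alone), with a list adjusted p of 2.56e-07 and adjusted p = 0.769 with an estimated correlation. Of 13 mitochondrially encoded genes 11 rose (12 adjusted over the list alone), with a list adjusted p of 9.06e-05 and adjusted p = 0.769 with an estimated correlation. Of 19 neuronal and synaptic genes 15 fell (18 adjusted over the list alone), with a list adjusted p of 2.42e-07 and adjusted p = 0.769 with an estimated correlation.

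With oil and hypoxia together, 17 of 19 cholesterol synthesis, 32 of 39 cell cycle and 5 of 6 red cell genes rose in post-hatch fish, and the list calls were lost with an estimated correlation (adjusted p = 0.266, 0.37 and 0.0856). The isoprenoid and sterol enzymes fdps, lss and ebp, gadl1 and the orphan nuclear receptor nr4a3 rose. The mitotic kinase plk1, the fatty acid importer cpt1a and slc4a1 rose, and calcoco1, usp13, the cytokine brake socs2 and the histidine-degrading enzyme hal fell. The combination raised 4398 genes and lowered 3878, of which 1411 changed at least 2-fold, and changed 3579 in the fit of all 36 libraries. Expression of fdps (NW_015150670.1, 1019295 to 1025936) rose from 5.73 ± 0.378 to 37.5 ± 5.87 CPM, a log2 change of 2.71 ± 0.15 (adjusted p = 2.77e-08). That of nr4a3 (NW_015150455.1, 2702354 to 2726386) rose from 5.63 ± 0.486 to 35.2 ± 10.2 CPM, a log2 change of 2.64 ± 0.18 (adjusted p = 1.45e-07). Log2 changes were 4.19 ± 0.25 for gadl1 (adjusted p = 3.26e-08), 2.84 ± 0.27 for lss (adjusted p = 2.05e-06), 2.19 ± 0.12 for slc4a1 (adjusted p = 1.27e-08) and 1.67 ± 0.14 for plk1 (adjusted p = 1.08e-06). It was -2.63 ± 0.21 for calcoco1 (adjusted p = 5.26e-07) and -1.61 ± 0.15 for hal (adjusted p = 1.56e-06). Of 19 cholesterol synthesis genes 17 rose (17 adjusted over the list alone), with a median log2 change of 1.26, a list adjusted p of 2.21e-13 and adjusted p = 0.266 with an estimated correlation. Of 39 cell cycle genes 32 rose and 1 fell (35 and 1 adjusted over the list alone), with a list adjusted p of 7.2e-15 and adjusted p = 0.37 with an estimated correlation. Of 6 red cell genes 5 rose (5 adjusted over the list alone), with a list adjusted p of 4.22e-05 and adjusted p = 0.0856 with an estimated correlation.

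In hypoxic post-hatch fish, oil raised the glycine-cleaving enzyme gldc and nr4a3 and lowered 16 of 62 ribosomal protein genes, a list call lost with an estimated correlation (adjusted p = 0.546). Oil under hypoxia raised 1726 genes and lowered 1504, but changed only 605 in the fit of all 36 libraries, where the interaction reached 4. On the log2 scale the change was 1.52 ± 0.09 for gldc (adjusted p = 2.1e-07) and 2.57 ± 0.18 for nr4a3 (adjusted p = 7.41e-07). For the epithelial growth factor fgf7 it was 2.00 ± 0.11 (adjusted p = 4.39e-08). However, 55.8% of its reads were uniquely placed and it lies inside dtwd1 on the same strand, so its change is uncertain. The call of fgf7 held with unique reads and with exon reads. The change of dtwd1 is uncertain too, at 1.41 ± 0.10 with all gene reads and -0.36 with exon reads alone. Of 5 AHR target genes 3 rose (3 higher and 1 lower adjusted over the list alone; list adjusted p = 1.25e-05; adjusted p = 0.0363 with an estimated correlation). Of 62 ribosomal protein genes 16 fell (33 adjusted over the list alone), with a list adjusted p of 3.37e-10 and adjusted p = 0.546 with an estimated correlation. The interaction, in which oxygen and the higher measured dose under hypoxia are not separated, reached 8 genes (1 higher, 7 lower). It was 1.73 ± 0.26 for nr4a3 (adjusted p = 0.0244), lost in 8 of 12 fits that left out 1 library (highest adjusted p 0.0983), and -1.93 ± 0.26 for ddit4 (adjusted p = 0.0215), lost in 3 (highest 0.0766). The oil under hypoxia count of 3230 was 1906 without hypoxic oil 3. The interaction count of 8 was 2, 0 and 0 without normoxic control 1, 2 and 3, 5, 3 and 3 without normoxic oil 1, 2 and 3, 38 without hypoxic control 3, and 26 and 5 without hypoxic oil 2 and 3; 1823 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 122.

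**Figure D3:**
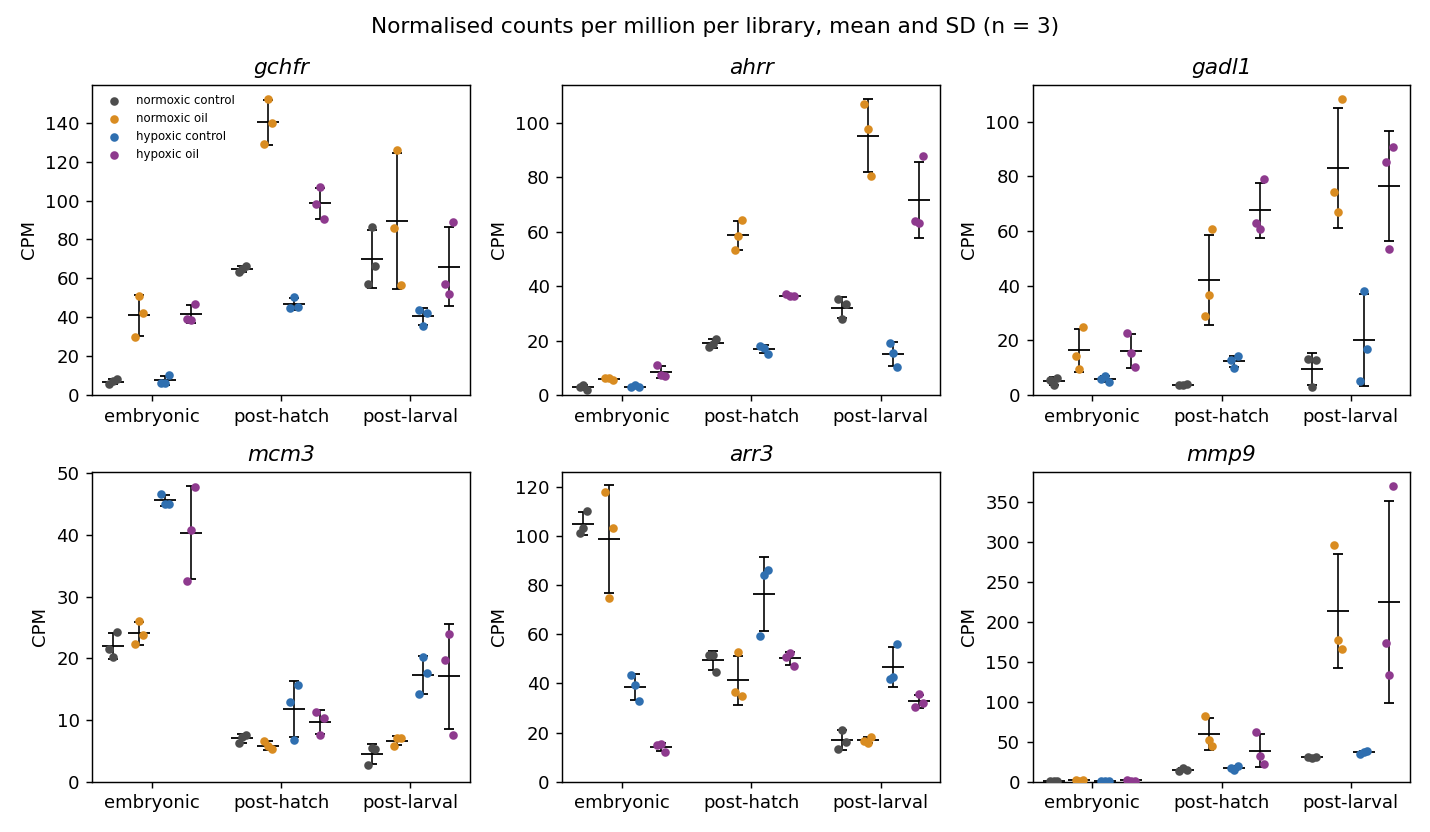
Points are libraries, with bars for the mean and SD of 3, in CPM (y axis), for 6 genes by stage (x axis) and treatment (colour). Under oil with hypoxia arr3 lay below the normoxic control in embryos, at 14.1 CPM, and ahrr lay above it at every stage.

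In post-larval fish, oil alone raised 16 of 19 cholesterol synthesis and 4 of 14 inflammatory genes, and both list calls were lost with an estimated correlation (adjusted p = 0.0846 and 0.0933). The sterol enzymes sqle, lss and msmo1, mmp9, gadl1 and the cytokine brake socs3 rose. Both AHR-induced genes, ahrr and tiparp, and the HIF target genes egln3 and vegfa, the vessel growth factor, rose, as did gsr. The brush border dipeptidase dpep1 and the aspartate aminotransferase got1 fell. Oil raised 828 genes and lowered 550, of which 521 changed at least 2-fold. Expression of sqle (NW_015150735.1, 824358 to 845142) rose from 4.43 ± 0.421 to 28.9 ± 11.5 CPM, a log2 change of 2.70 ± 0.25 (adjusted p = 0.000127). That of mmp9 (NW_015150638.1, 876231 to 880810) rose from 30.6 ± 0.558 to 214 ± 71.8 CPM, a log2 change of 2.80 ± 0.33 (adjusted p = 0.000664). The log2 change was 2.37 ± 0.23 for msmo1 (adjusted p = 0.000151), 1.47 ± 0.15 for socs3 (adjusted p = 0.000209), 1.11 ± 0.16 for gsr (adjusted p = 0.00224), -1.98 ± 0.30 for dpep1 (adjusted p = 0.00288) and -1.61 ± 0.23 for got1 (adjusted p = 0.00232). Of 19 cholesterol synthesis genes 16 rose (18 adjusted over the list alone), with a median log2 change of 1.24, a list adjusted p of 9.55e-31 and adjusted p = 0.0846 with an estimated correlation. Of 14 inflammatory and acute phase genes 4 rose (7 adjusted over the list alone), with a list adjusted p of 6.3e-08 and adjusted p = 0.0933 with an estimated correlation. Of 14 NRF2 target genes 5 rose (8 higher and 1 lower adjusted over the list alone), with a list adjusted p of 0.000131 and adjusted p = 0.0933 with an estimated correlation. Of 19 HIF target genes 4 rose (6 adjusted over the list alone), with a list adjusted p of 0.000895 and adjusted p = 0.0846 with an estimated correlation. The count of 1378 was 545, 588 and 802 without normoxic control 1, 2 and 3 and 462 and 572 without normoxic oil 1 and 3.

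Hypoxia alone raised 11 of 19 cholesterol synthesis and 10 of 39 cell cycle genes in post-larval fish, and both list calls were lost with an estimated correlation (adjusted p = 0.55 and 0.776). The myosin chaperone unc45b, the mitochondrial chaperone hspd1, the serine synthesis enzymes phgdh and psat1 and mcm3 rose. Unlike in embryos, the cone genes pde6h and arr3 rose. The cartilage matrix protein matn1, the muscle glycolysis enzyme pfkm and the AHR repressor ahrr fell. Hypoxia raised 1135 genes and lowered 1097, of which 633 changed at least 2-fold. Expression of unc45b (NW_015151271.1, 302063 to 310220) rose from 9.53 ± 1.2 to 173 ± 109 CPM, a log2 change of 4.18 ± 0.55 (adjusted p = 0.00252). That of pde6h (NW_015151296.1, 28660 to 29959) rose from 51.1 ± 3.15 to 194 ± 27.4 CPM, a log2 change of 1.92 ± 0.14 (adjusted p = 5.46e-05). Log2 changes were 1.95 ± 0.36 for mcm3 (adjusted p = 0.00843), 1.05 ± 0.17 for psat1 (adjusted p = 0.00553), 1.19 ± 0.20 for hspd1 (adjusted p = 0.00598), -1.83 ± 0.37 for matn1 (adjusted p = 0.0113) and -1.10 ± 0.14 for pfkm (adjusted p = 0.00247). Of 19 cholesterol synthesis genes 11 rose (14 adjusted over the list alone), with a list adjusted p of 2.49e-13 and adjusted p = 0.55 with an estimated correlation. Of 39 cell cycle genes 10 rose (16 adjusted over the list alone), with a list adjusted p of 3.56e-08 and adjusted p = 0.776 with an estimated correlation. Of 50 nuclear oxidative phosphorylation genes 7 fell (9 adjusted over the list alone), with a list adjusted p of 7.89e-05 and adjusted p = 0.892 with an estimated correlation. Of 18 photoreceptor genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with a list adjusted p of 0.00117 and adjusted p = 0.776 with an estimated correlation. The count of 2232 was 1087, 870 and 864 without normoxic control 1, 2 and 3 and 1019 and 350 without hypoxic control 2 and 3.

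The combination in post-larval fish raised the red cell gene slc4a1, 18 of 19 cholesterol synthesis and 25 of 39 cell cycle genes and lowered the thyroid hormone precursor tg and got1. Both list calls were lost with an estimated correlation (adjusted p = 0.134 and 0.413). The retinoid carrier rbp7, mmp9, the muscle protein klhl40 and the cell cycle activator e2f1 rose, as did the bone phosphatase alpl. Together the stressors raised 2237 genes and lowered 1900, of which 1232 changed at least 2-fold. Expression of slc4a1 (NW_015150521.1, 96926 to 105690) rose from 2.85 ± 0.831 to 44.8 ± 15.5 CPM, a log2 change of 3.97 ± 0.48 (adjusted p = 0.000399). On the log2 scale the change was 2.88 ± 0.33 for mmp9 (adjusted p = 0.000265), 2.20 ± 0.23 for msmo1 (adjusted p = 0.000162), 1.84 ± 0.31 for e2f1 (adjusted p = 0.00232) and 1.25 ± 0.15 for alpl (adjusted p = 0.000356). It was -2.11 ± 0.23 for got1 (adjusted p = 0.00023) and -1.75 ± 0.36 for tg (adjusted p = 0.00635). Of 19 cholesterol synthesis genes 18 rose (18 adjusted over the list alone), with a median of 1.59, a list adjusted p of 8.98e-24 and adjusted p = 0.134 with an estimated correlation. Of 39 cell cycle genes 25 rose (33 adjusted over the list alone), with a list adjusted p of 2.54e-13 and adjusted p = 0.413 with an estimated correlation. Of 6 red cell genes 5 rose (5 adjusted over the list alone), with a list adjusted p of 6.56e-05 and adjusted p = 0.134 with an estimated correlation. The count of 4137 was 2371 and 2648 without normoxic control 1 and 3 and 2143 without hypoxic oil 2.

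Oil in hypoxic post-larval fish raised ahrr, gsr and the hepatic lipase lipc. Oil under hypoxia raised 590 genes and lowered 327, against 698 and 680 in the fit of all 36 libraries and 1659 in all in DESeq2. Expression of ahrr rose from 15 ± 4.32 to 71.7 ± 14 CPM, a log2 change of 2.25 ± 0.21 (adjusted p = 0.000103). The log2 change was 1.46 ± 0.16 for gsr (adjusted p = 0.00033) and 1.36 ± 0.16 for lipc (adjusted p = 0.000653). It is uncertain for the overlapping genes fgf7, at 2.67 ± 0.14 (adjusted p = 3.01e-07), and dtwd1, at 1.78 ± 0.18 with all gene reads and -0.24 with exon reads. Of 5 AHR target genes 2 rose (3 adjusted over the list alone), with a list adjusted p of 0.000133 and adjusted p = 0.0808 with an estimated correlation. Of 18 photoreceptor genes 2 fell (10 adjusted over the list alone), with a list adjusted p of 3.76e-05 and adjusted p = 0.311 with an estimated correlation. No interaction was called by edgeR, against 1299 genes at an unadjusted p under 0.05 and 41 called by DESeq2. The interaction count was 15 without hypoxic oil 1, 3 with the replicate block and 27 in the fit of all 36 libraries. The oil under hypoxia count of 917 was 512, 435 and 357 without hypoxic control 1, 2 and 3 and 439 without hypoxic oil 3.

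**Figure D4:**
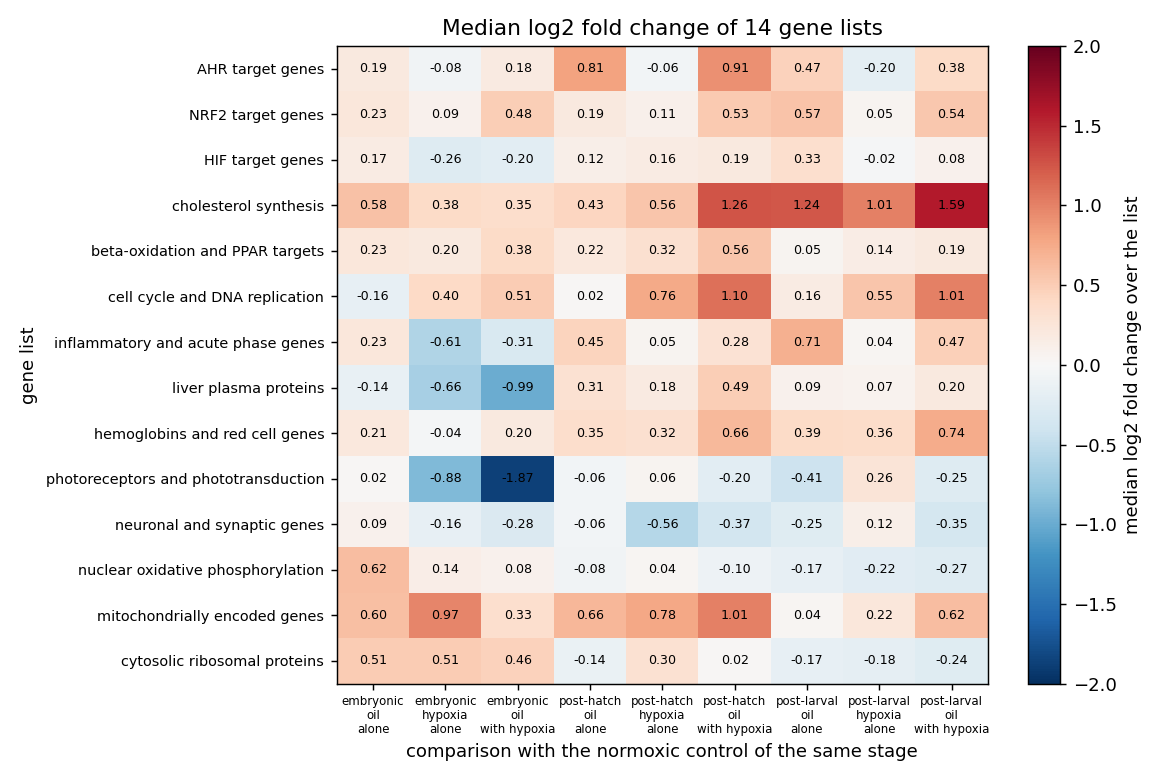
Cells give the median log2 fold change over the measured members of 14 gene lists (y axis) in each comparison with the normoxic control (x axis), on a colour scale from -2 to 2. Cholesterol synthesis lay at 1.24 under oil and 1.59 under oil with hypoxia in post-larval fish, and photoreceptors at -1.87 in embryos under oil with hypoxia.

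Across stages, oil raised the AHR-induced genes ahrr and tiparp after hatching. Hypoxia alone raised neither egln3 nor vegfa, the HIF targets given in every comparison, at any stage. This does not speak for other HIF target genes. The AHR repressor was called higher under oil with hypoxia in embryos (log2 change 1.56 ± 0.28, adjusted p = 0.00796), in post-hatch fish (0.95 ± 0.10, adjusted p = 3.81e-06) and in post-larval fish (1.16 ± 0.20, adjusted p = 0.0032). Under oil alone its log2 change was 1.02 ± 0.28 in embryos, where it was not called (adjusted p = 0.246), and 1.57 ± 0.21 in post-larval fish (adjusted p = 0.00131). In embryos its oil libraries, at 5.31 to 6.17 CPM, all lay above the normoxic controls, at 1.87 to 3.67 CPM. A rise there is therefore not excluded. Hypoxia alone lowered ahrr in post-larval fish (-1.10 ± 0.21, adjusted p = 0.00928). For tiparp, the log2 change under oil was 0.23 ± 0.12 in embryos (adjusted p = 0.428), 0.91 ± 0.08 in post-hatch fish (adjusted p = 6.71e-06) and 1.14 ± 0.15 in post-larval fish (adjusted p = 0.00121). Oil alone also raised egln3 in post-hatch (1.13 ± 0.16, adjusted p = 0.000415) and post-larval fish (1.94 ± 0.31, adjusted p = 0.00371), and vegfa in post-larval fish (0.97 ± 0.16, adjusted p = 0.00519). Under oil with hypoxia egln3 fell in embryos (-2.79 ± 0.26, adjusted p = 0.000182) and rose in post-hatch fish (0.93 ± 0.16, adjusted p = 0.000344). Its rise in post-larval fish (1.23 ± 0.31, adjusted p = 0.016) was lost in 3 of 12 fits that left out 1 library (highest adjusted p 0.0678). Under hypoxia alone, the adjusted p of egln3 was 0.548 in post-hatch and 0.375 in post-larval fish, and that of vegfa was 0.961, 0.19 and 0.405 from the youngest stage to the oldest.

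The response to each stressor differed between stages for gldc, selenbp1, arr3 and clcn1, among others. Oil raised selenbp1 in embryos and gldc in post-hatch fish, and lowered gldc in post-larval fish. Cone arrestin fell under hypoxia in embryos and rose in post-larval fish. The effect of oil depended on stage in 1418 of 21877 genes, that of hypoxia in 1802 and that of both in 3641. For oil and hypoxia these were 3180 and 2781 with the replicate block and 2540 and 2869 in DESeq2. For gldc the log2 change under oil was 0.21 ± 0.15 in embryos and 1.39 ± 0.09 in post-hatch fish, and it fell in post-larval fish (adjusted p = 0.0107; adjusted p = 3.39e-07 for the difference between stages), and for selenbp1 it was 2.48 ± 0.21, 0.25 ± 0.13 and 0.01 ± 0.22 (adjusted p = 8.59e-06). Under hypoxia it was -1.44 ± 0.18, 0.63 ± 0.15 and 1.47 ± 0.17 for arr3 (adjusted p = 1.24e-07). Under both it was -5.28 ± 0.49, 0.52 ± 0.14 and -0.08 ± 0.24 for clcn1 (adjusted p = 1.17e-09). Measured oil differed between the stages, so these differences are between stages at different doses. The oil count of 1418 was 658, 941 and 3750 without embryonic normoxic control 1, 2 and 3, 886 and 752 without embryonic normoxic oil 2 and 3, 3005 without embryonic hypoxic control 3, 916 and 945 without post-larval normoxic control 1 and 2, and 832 and 890 without post-larval normoxic oil 1 and 3. The hypoxia count of 1802 was 1172 without embryonic normoxic control 1, 3002 without embryonic hypoxic control 1, and 1199 and 1103 without post-hatch normoxic control 1 and 2.

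Few genes were called at every stage under oil or hypoxia alone, and more under both stressors, where more were called in each stage. The replication helicase genes mcm3 and mcm6 were the only symbol-bearing genes called higher under hypoxia at every stage, with 2 LOC genes beside them. Under oil, lipc and rgn, a calcium-binding liver protein, were called higher at every stage, with 14 LOC genes, and 1 LOC gene was lower. Under both stressors 58 symbol-bearing genes, among them ahrr, gadl1, gsr and mcm2, were higher at every stage and 25 were lower, among them the muscle genes des and pfkm and the photoreceptor gene rom1. The 58 include the overlapping genes fgf7 and dtwd1, whose changes are uncertain. Refitted with each of the 36 libraries left out, mcm3 was no longer called at every stage in 7 fits and mcm6 in 5 (highest adjusted p 0.137 and 0.142), and without embryonic hypoxic control 2 no gene was under hypoxia. Likewise lipc was lost in 8 fits and rgn in 12 (0.208 and 0.168), gadl1 in 4, mcm2 in 5 and des in 12 (0.111, 0.118 and 0.124). With LOC genes, 94 were higher and 70 lower under both stressors at every stage. These counts ranged over 27 to 144 and 37 to 104 in such fits, and 18 and 12 genes kept the call in every fit. The 16 genes higher under oil ranged over 6 to 18, with 5 kept in every fit. The log2 change of rgn under oil was 1.89, 1.53 and 1.28 from embryonic to post-larval fish, and that of mcm6 under hypoxia was 0.94, 0.96 and 1.51. Between post-hatch and post-larval fish, 251 genes were higher under oil in both (46.9 if the calls were independent), 482 under hypoxia (193) and 1389 under both stressors (456). In the fit of all 36 libraries these were 100, 246 and 906. The correlation of log2 changes across genes, which are not independent replicates, was 0.307, 0.188 and 0.513 in that order between post-hatch and post-larval fish. Between embryonic and post-hatch fish it was 0.086, 0.083 and 0.078. Between embryonic and post-larval fish it was -0.026 for oil, 0.22 for hypoxia and 0.181 for both stressors. For hypoxia it was thus higher between embryonic and post-larval fish than between post-hatch and post-larval fish. Of the genes called under both stressors in embryonic and post-hatch fish, 258 of 586 went opposite ways, against 115 of 2635 in post-hatch and post-larval fish.

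Oil and hypoxia shared their control libraries. In post-hatch fish 484 genes were higher under each (203 if independent) and 124 lower (about 1.0e+02), with 218 of 826 in opposite directions. In post-larval fish 85 were higher (44.3) and 125 lower (28.5), with 40 of 250 opposite, and in embryos none were shared in the same direction and 2 were opposite. The fit of all 36 libraries gave 62 higher and 4 lower in post-hatch fish, 136 and 192 in post-larval fish and 21 and 60 in embryos. Unchanged groups simulated against the same controls shared 0 calls, but groups without change have hardly a call to share, so this is no chance level for the overlap of real effects. The correlation of log2 changes across genes was 0.27, 0.247 and 0.3 from embryonic to post-larval fish, against 0.501, 0.496 and 0.508 in the simulations, and the covariance was 0.0757, 0.0462 and 0.078 against 0.0826, 0.0228 and 0.043. The 3 controls are too few to split, so part of any excess over independent calls may come from the shared controls.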

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

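Of the tests in this part, those of intron reads and library size, of exchanged libraries, of the first principal component, of eye and liver tissue and of shared reads were chosen after the results they test were seen. The tests of development and of other splits of the libraries were written down earlier. So was a test of library size by the biological coefficient of variation after thinning, which could not have come out otherwise and was replaced.

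The effect of oil differed between oxygen levels in 22 genes in embryos and 8 in post-hatch fish. Measured oil was also higher under hypoxia than under normoxia in both stages, so oxygen and dose cannot be told apart here. In embryos the ankyrin repeat gene ankrd9, the muscle genes hspb6 and pfkm, the purine enzyme gmpr and the potassium channel kcnj11 each had an adjusted p of 0.0164, with interactions of -2.94, -2.50, -2.64, -3.41 and -1.56 on the log2 scale. Of the 12 fits that each left out 1 library, ankrd9 lost its call in 5 (highest adjusted p 0.0705), hspb6 in 4 (0.0744), pfkm in 6 (0.0744), gmpr in 8 (0.0759) and kcnj11 in 6 (0.0931). In post-hatch fish the interaction was -1.93 for ddit4 (adjusted p = 0.0215), 1.73 for nr4a3 (adjusted p = 0.0244) and -0.86 for the NAD kinase nadk (adjusted p = 0.0342), lost in 3, 8 and 9 fits (highest 0.0766, 0.0983 and 0.101). The other genes of the 8 have no symbol. The embryonic count was 226 with the replicate block, 261 in DESeq2 and 477 in 1 fit of all 36 libraries. It was 14, 6 and 12 without normoxic control 1, 2 and 3, 5, 39 and 5 without normoxic oil 1, 2 and 3, 36 without hypoxic control 3, and 11 and 5 without hypoxic oil 1 and 2. The post-hatch count was 2, 0 and 0 without normoxic control 1, 2 and 3, 5, 3 and 3 without normoxic oil 1, 2 and 3, 38 without hypoxic control 3, and 26 and 5 without hypoxic oil 2 and 3 (1823 genes at an unadjusted p under 0.05 in edgeR with all libraries; 122 called by DESeq2).

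Other ways of assigning the 12 libraries of a stage were tried 60 times, the real one included. For embryos 1 of 60 gave as many genes, the real one with 22, and the highest of the others was 0. These splits also mix the effects of oil and of hypoxia into the groups, which widens the spread within them. A count of 0 in them therefore cannot exclude chance for the interaction. For post-hatch fish 2 of 60 did, the real one with 8 and another with 2478. That other split sets oil against control and follows the oil effect itself. Chance cannot be excluded there either, for the same reason. For post-larval fish, where edgeR called 0 (1299 at an unadjusted p under 0.05; 41 in DESeq2), all 60 reached that count, as any split must, so the splits say nothing of chance there. The highest other, 2151, sets hypoxic against normoxic libraries.

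The stage changed the effect of oil in 1418 genes, of hypoxia in 1802 and of both in 3641. Oil raised gldc after hatching and lowered it in post-larval fish (adjusted p = 3.39e-07 for a difference between stages), and raised selenbp1 in embryos (8.59e-06) and klf13 in post-hatch fish (0.000104). The secreted protein angptl5 (1.73e-05) had log2 changes of -0.11, 1.12 and 2.90 from embryonic to post-larval fish, and the clock factor dbp (9.44e-05) of 0.59, 0.73 and -0.92. Under hypoxia the cone genes arr3 (1.24e-07) and pde6h (3.21e-06) had log2 changes below 0 in embryos and above 0 in post-larval fish. The proteasome genes psmd1 (9.65e-06) and psmd14 (1.43e-05) and the Golgi gene cog4 (1.33e-05) had them above 0 in embryos and below 0 after hatching. Under both stressors arr3 (7.42e-11), the transcription factor klf11 (7.04e-10), clcn1 (1.17e-09), the carotenoid enzyme bco2 (2.61e-09) and cog4 (3.18e-09) differed between stages. The reads of psmd1 and cog4 are uncertain, since each overlaps a gene on the opposite strand. Measured oil differed between stages as well, so dose and stage cannot be told apart for oil.

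The oil count of 1418 was 658, 941 and 3750 without embryonic normoxic control 1, 2 and 3, 886 and 752 without embryonic normoxic oil 2 and 3, 3005 without embryonic hypoxic control 3, 916 and 945 without post-larval normoxic control 1 and 2, and 832 and 890 without post-larval normoxic oil 1 and 3. The hypoxia count of 1802 was 1172 without embryonic normoxic control 1, 3002 without embryonic hypoxic control 1, and 1199 and 1103 without post-hatch normoxic control 1 and 2. Over 30 ways of assigning the libraries within stages, 1 reached the real count for oil (1418, highest other 334) and 1 for both stressors (3641, highest other 2103). These ways exchange exposed and control libraries, which removes the effect of the stressor itself. Lower counts in them therefore do not exclude chance for a difference between stages. For hypoxia 3 of 30 reached the real 1802, the others with 5501 and 4707, so chance cannot be excluded. Each of these others keeps or mirrors the real hypoxia split in some stage. Their counts may come from a real effect set against none, which was not tested.

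Reads from introns, which are part of the gene counts tested and whose share no comparison tests, took a larger share in every library of 3 groups than in the normoxic controls of their stage. The share was 8.57% ± 1.19 in embryonic hypoxic controls, against 6.93% ± 0.367 in normoxic ones. In post-hatch fish it was 4.87% ± 0.0832 under hypoxia and 5.52% ± 0.13 under oil with hypoxia, against 4.06% ± 0.196 (SD, n = 3 each).

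The embryonic replicates were spread along the first principal component. Genes that set hypoxic control 3 apart also set normoxic control 3 apart (r = 0.721 across genes), and they resembled the difference of normoxic oil from normoxic controls 1 and 2, with control 3 left out (r = 0.744). Reads in introns and library size do not make up the spread themselves. The SD within groups on this component was 56.6 with exon reads thinned to 1 size, against 55.1 with all gene reads. This does not exclude a difference between samples that goes with the intron share. From replicate 1 to 3 that share was 6.54%, 6.98% and 7.27% in normoxic and 7.28%, 8.80% and 9.64% in hypoxic controls. It rose with the position on the component there and under oil with hypoxia, but not under oil alone. An exchange of either control 3 with an oil library is argued against by 100 genes that rose under oil at both oxygen levels in both later stages, whose mean log2 level was lower in both than in the lowest of the 6 oil libraries by at least 0.447 (SD of oil libraries within groups 0.184), but this set and its bound were chosen after 3 sets had been tried, and the gap was 0.297 for AHR target genes and 0.159 for genes higher under oil alone in both later stages. Development at different rates may play a part, but the deviation had a correlation of -0.185 across genes with the change from embryonic to post-hatch controls, which does not decide it.

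Photoreceptor genes had a median log2 change of -1.87 in embryos under oil with hypoxia. The lens genes argue against a smaller share of eye tissue as the whole cause, with a median of -0.017 (7 genes, -0.15 to 0.56). With the replicate block 17 of 17 photoreceptor genes were called lower. Every group holds each replicate number, so the block hardly shifts a group difference and cannot test the position on the first component. Slower development may contribute. A set of 1871 genes at least 4-fold higher in post-hatch normoxic controls than in embryonic normoxic oil libraries had a median of -0.37 (quartiles -0.83 and 0.04). Of these, 73.6% were lower. Such a set also takes in genes that oil itself lowers in embryos, so its fall does not decide the question. However, photoreceptor genes themselves differed by a median of only 0.05 between post-hatch and embryonic controls. Their course before the embryonic sampling was not measured, so this does not exclude a delay. The 7 lens genes, all called higher in post-hatch than in embryonic controls (median 1.86), were not lower as a list here. Slower development therefore stays open, as does the first component, beside a direct effect on photoreceptors, which was not tested.

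Cholesterol synthesis genes had a median log2 change of 1.24 in post-larval fish under oil. A larger share of liver tissue would raise plasma proteins of the liver, whose median was 0.089 (18 genes, quartiles -0.13 and 0.32). Counting exon reads alone left 16 of 19 called higher, as did uniquely placed reads alone, again 16, so neither intron reads nor shared reads account for it. A response of sterol synthesis to oil may be the cause, as a hypothesis found and tested on the same data.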

How the results depend on the processing

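Counting exon reads only and leaving out the 2 embryonic controls that stood apart were chosen after seeing the data. With RLE factors and with unique reads, all 20 counts of genes stayed within 1.5 times. Of the 24 overlaps of calls, counted by direction, 22 left that range in 1 fit of all 36 libraries, 17 with the replicate block and 15 in DESeq2. Changes of counts had no tested cause, except where libraries or genes were fewer.

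With the replicate block, the embryonic counts became 508, 641, 2330, 248 and 226 for oil, hypoxia, both, oil under hypoxia and the interaction, the post-larval interaction 3, and the stage-dependent counts 3180 for oil and 2781 for hypoxia. DESeq2 gave embryonic counts of 276, 603, 1916, about 3.4e+02 and 261 in that order, 122 for the post-hatch interaction, 1659 for post-larval oil under hypoxia, 41 for the post-larval interaction, and 2540 and 2869 for stage-dependent oil and hypoxia. Without a low-count filter, and with exon reads, the post-larval interaction count was 2. One fit of all 36 libraries gave 1353, 1133, 3148, 446 and 477 in embryos, 356, 1805, 3579, 605 and 4 in post-hatch fish, and 1378 and 27 for post-larval oil under hypoxia and interaction. Without embryonic normoxic control 3 and hypoxic control 3 together the embryonic counts were 4994, 71, 3535, 138 and 70; these libraries were picked for their position, so this shows only dependence on them. The cause of these changes was not tested.

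The share of higher genes under embryonic oil, 84.8%, was 65.4% with the block, 73.6% in DESeq2, 49.4% without the libraries that stood apart and 46.8% in the joint fit. For embryonic hypoxia, 40.5% became 52.1% with the block and 55.1% in DESeq2. For both stressors in embryos it went from 36.9% to 53.2% without the libraries that stood apart, and for embryonic oil under hypoxia from 42.9% to 32.7% with the block. In the joint fit it went from 66.4% to 77.5% for post-hatch oil and from 64.3% to 50.7% for post-larval oil under hypoxia.

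Leaving out 1 library at a time, embryonic counts ranged over 18 to 202, 0 to 59, 443 to 1688, 43 to 90 and 5 to 39, post-hatch counts over 1095 to 2110, 5071 to 7328, 6552 to 8961, 1906 to 3212 and 0 to 38, and post-larval counts over 462 to 1679, 350 to 2888, 2143 to 4499, 357 to 1358 and 0 to 15. Stage-dependent counts ranged over 658 to 3750 for oil, 1103 to 3002 for hypoxia and 2703 to 4531 for both, and the control comparisons over 13070 to 14771 and 4694 to 7926.

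With exon reads the log2 change of dtwd1 under oil in hypoxia reversed. It went from 1.41 to -0.36 in post-hatch fish (adjusted p = 0.103) and from 1.78 to -0.24 in post-larval fish (adjusted p = 0.585). The rise in its gene reads was thus not a rise in its exon reads. Of its gene reads 70.1% lay in introns, and fgf7, which also rose, lies inside it on the same strand. Whether reads of fgf7 made the rise was not tested. Of 294 called results for named genes, 219 kept the call with every library left out and 255 under every other setting. The joint fit ended 28 such calls, the block 6 and exon reads 7, among them the 2 of dtwd1. With an estimated correlation 152 of 495 list results lost their call and 343 kept their side of the threshold. For oil alone in embryos, with 12018712 to 23042839 reads and a biological coefficient of variation of 0.274, 14.9% of simulated 2-fold changes were recovered. In post-larval fish, with 13263290 to 17762109 reads and a coefficient of 0.185, 59.7% were.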

Other observations

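The splits in this part were planned. Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In embryos the real and the highest other counts were 66 and 0 for oil, 42 and 1486 for hypoxia, 1076 and 0 for oil with hypoxia, and 91 and 0 for oil under hypoxia. In post-hatch fish they were 1819 and 1, 7400 and 0, 8276 and 0, and 3230 and 0 in the same order, and in post-larval fish 1378 and 0, 2232 and 1, 4137 and 0, and 917 and 0. Between normoxic controls they were 14074 and 0, and 6803 and 0. For embryonic hypoxia 2 of 10 splits reached the real count, and in every other comparison 1 did. The split with 1486 genes sets normoxic control 1 and 2 and hypoxic control 1 against the rest and parts 1 same-numbered pair; its count points to a structure of the libraries. The 3 other splits that part every pair, as the real one does, gave 0 genes in edgeR. The blocked fit gave 641 genes for embryonic hypoxia, and without hypoxic control 2 the count was 0, with a log2 change of -1.80 for mlip against -1.88 with it (2507 genes at an unadjusted p under 0.05 with all libraries; 603 called by DESeq2).

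Mitochondrially encoded genes took 1.49% ± 0.257 of the gene reads in embryonic normoxic controls, 2.6% ± 0.645 under hypoxia, 1.78% ± 0.11 under oil and 2.01% ± 0.237 under both (SD, n = 3). In the same order the share was 1.28% ± 0.196, 1.91% ± 0.108, 1.98% ± 0.64 and 2.27% ± 0.184 in post-hatch fish, and 2.05% ± 0.488, 1.94% ± 0.0977, 2.21% ± 0.17 and 2.56% ± 0.0543 in post-larval fish. Within dtwd1, 70.1% of the gene reads lay in introns, against 1.39% in fgf7, which lies inside it on the same strand.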
